A study of Homo sapiens with 8 samples.

How the data were processed

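Poly(A) sites, the positions where transcripts are cleaved and receive their poly(A) tail, were profiled in 2 human cell lines with 4 libraries each. HCT116 is a colorectal carcinoma line that the labels describe as able to methylate its DNA. DKO is a line derived from HCT116 in which the DNA methyltransferase genes DNMT1 and DNMT3B were knocked out, described in the labels as defective in DNA methylation. The series' design text calls the 4 libraries of each line biological replicates. Groups and replicate numbers were taken from the sample titles.

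Per the labels' protocols, poly(A)+ RNA was fragmented, short fragments were cut from a gel, and cDNA was primed with an anchored oligo(dT) primer that carried a sample barcode and a stretch of degenerate bases. The submitters' processing notes name Bowtie2 version 2.2.5 and the hg19 build. How processing regions were called, how reads primed inside A-rich transcript sequence or mapping to several places were treated, and whether the degenerate bases were used to remove PCR duplicates are not given in the sources used here. Internal priming would add false sites, PCR duplicates would add spread between libraries, and reads from near-identical copies could be split between them or lost.

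The deposited table gives whole-number read counts per poly(A) processing region, not scaled between libraries, with chromosome, start, end and strand and no gene name. It holds 37107 regions, 18837 on the plus strand and 18270 on the minus strand, with a median span of 26 nt. The smallest total of a region over the 8 libraries was 15 counts and the median total was 179 counts. All 8 count columns matched a sample title. Coordinates are given as deposited, on hg19; whether starts are counted from 0 or 1 is not given in the sources used here.

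No hg19 annotation and no genome sequence was used here, since the gene tables at hand were on another build and coordinates were not converted. Genes were therefore replaced by loci, defined as runs of regions on one strand with gaps of at most 5000 nt between neighbours. This gave 21348 loci, of which 14040 had 1 region and 7308 had 2 or more, up to 30. A locus can join neighbouring genes or divide a long one, so a shift between 2 regions of a locus need not be a shift within 1 gene. The gene lists, the region classes (intron, coding exon, 3' UTR), and the genes set to be named in every case (DNMT1, DNMT3B, DNMT3A, CTCF, RAD21 and HEATR2) could not be placed on the regions and were not analysed here. The knockout of the targeted genes was for the same reason not checked.

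Counts were analysed with edgeR version 4.0.16 and limma version 3.58.1 in R version 4.3.3; DESeq2 version 1.42.0 served as an alternative, and figures were drawn with matplotlib version 3.10.9. Low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total count 15) and libraries were scaled by TMM. For locus totals, the counts of all regions of a locus were summed and DKO was compared with HCT116 by the quasi-likelihood test (glmQLFit and glmQLFTest). CPM values are relative to the TMM-scaled library totals. For usage, each kept region was compared with the rest of its locus (diffSpliceDGE), with Simes p-values per locus. For direction, the 2 regions of a locus with the highest mean share over all 8 libraries were taken, proximal being the one nearer the transcription start by strand. The ratio of distal to proximal counts was also tested with diffSpliceDGE, but by its F test per locus and not by Simes p-values. All adjusted p-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. The change of a single region was taken as the difference of mean log2 CPM with 0.5 counts added. The median over loci of the distal share was computed per library, and the lines were compared by an exact permutation test, two-sided, whose smallest possible p with 4 against 4 libraries is 0.0286.

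Where a line had 0 counts in all 4 libraries, the fold was computed against a floor of 3 counts over the 4 libraries of the line and is a lower bound. With 1 or more counts, the ratio of pooled scaled counts is given with an exact 95% binomial interval. Intervals and floors cover counting error only, since reads need not be independent molecules.

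The loci described singly were fixed by a rule written before the data were examined. For totals it takes the 12 loci with the highest and the 12 with the lowest log2 fold change among those with adjusted p under 0.05, at least 5 CPM in the higher line and no overlap between the libraries of the lines. For usage it takes the 12 largest falls and the 12 largest rises of the distal share among loci with adjusted p under 0.05, at least 50 counts per library on average in the 2 regions and no overlap between the lines. Of the 12 lowest totals, 2 lie on chromosome Y, and their levels are not given here.

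Replicates of a line were compared with each other first. The chi-square per degree of freedom was computed over loci with at least 20 counts in the 2 compared libraries together. It was 1.41 to 4.98 between replicates 1 and 2 or between 3 and 4 of a line, and 11.6 to 20.3 between these pairs, so no 2 libraries agreed within sampling noise. Replicate numbers are shared by the lines. Deviations from the mean of the line correlated at 0.802 to 0.843 between libraries with the same number. The correlations were 0.780 to 0.825 between different numbers within replicates 1 and 2 or within 3 and 4, and -0.839 to -0.788 across these pairs. The numbers were therefore treated as pairing the libraries through a split of replicates 1 and 2 from 3 and 4, which the labels do not mention. Fits with the replicate number as a block are given beside summary results that they moved by more than 1.5 times, as are values within each pair of replicates. For loci described singly, values within the pairs are given for some loci only.

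The tests were run on simulated counts with a seeded set of items changed by known sizes. Counts were drawn without the split between replicates and with dispersions estimated under the replicate block. The fits had no block, so the rates below leave out the spread that the split adds to the real libraries. For locus totals, 83.0% of changes of log2 size 1 and 100% of size 2 were recovered, with 8 false calls over 17280 tested loci. For the 2 most used regions, 67% of changes of log2 size 1 and 96% of size 2 were recovered, with 8 false calls over 6140 loci. For usage over all regions, 44.1% of changes of log2 size 1 and 94.6% of size 2 were recovered, with 2 false calls over 6031 loci.

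Alternatives were median-ratio (RLE) scaling, no low-count filter, the replicate block, each library left out in turn, DESeq2, a fold or share minimum, removal of regions under 5% of their locus, merging of regions within 100 nt, the first and last region in place of the most used, and, for the distal share, the mean over loci or only loci with at least 50 counts in every library. After the data were examined, fits within replicates 1 and 2 or 3 and 4, a block for these pairs, thinning of all libraries to the smallest total, locus gaps of 2000 or 10000 nt, pairs at most 1000 nt apart and limma on log2 ratios were added.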

Results

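Poly(A) site sequencing of HCT116 and its derivative DKO, described as knocked out for DNMT1 and DNMT3B, addressed whether defective DNA methylation is accompanied by a change in where transcripts are cleaved and polyadenylated. Each line had 4 libraries. The HCT116 libraries held 8261472, 6143168, 5261161 and 4335757 counts for replicates 1 to 4, and the DKO libraries held 3079424, 4533831, 3353491 and 2545983. In a single library 3 counts corresponded to between 0.363 CPM in the deepest and 1.18 CPM in the shallowest, relative to unscaled totals; the bounds on folds use 3 counts summed over the 4 libraries of a line. Counts were spread over 37107 processing regions, and the 100 most used regions took 18.2% to 19.9% of the counts in HCT116 and 14.1% to 16.3% in DKO.

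The lines separated on the first principal component of locus log2 CPM, which held 54.2% of the variance. The second component held 39.4% and separated replicates 1 and 2 from replicates 3 and 4 in both lines. Regions with 0 counts followed the same split. They numbered 1025 and 810 in HCT116 replicates 1 and 2 against 2578 and 3623 in replicates 3 and 4. In DKO they numbered 548 and 317 against 3153 and 3758. The calls were therefore also counted within each pair of replicates.

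**Figure D1:**
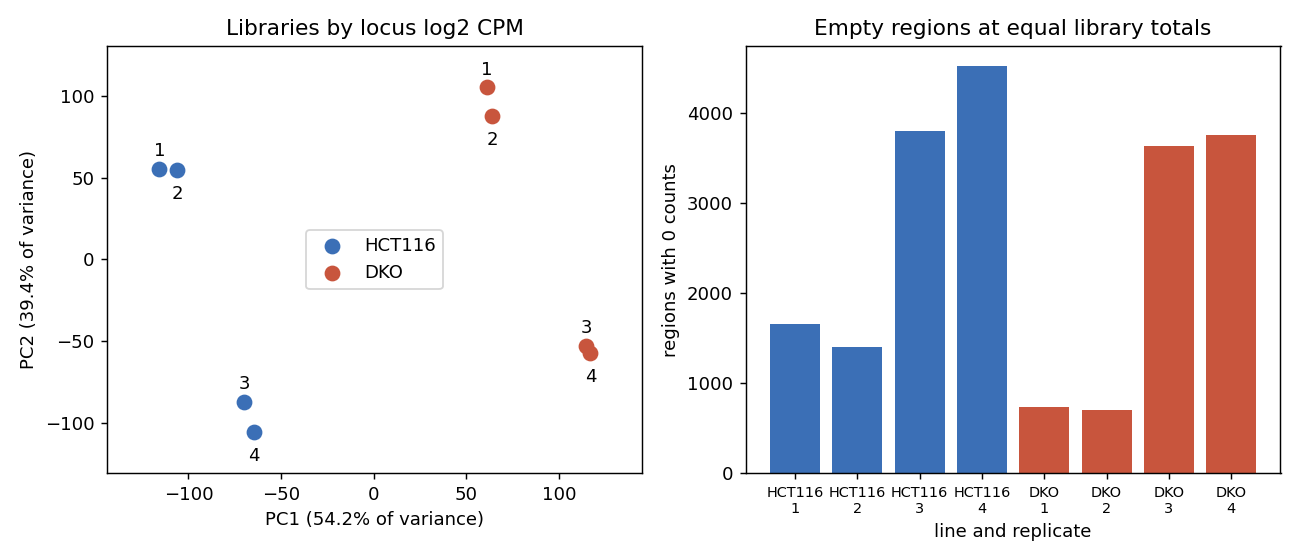
Left, scores of the 8 libraries on the first 2 principal components of locus log2 CPM, numbered by replicate and coloured by line (percent of variance on the axes). Right, number of regions with 0 counts per library after all libraries were thinned to 2545983 counts; replicates 3 and 4 had 3633 to 4524 empty regions and replicates 1 and 2 had 699 to 1661.

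In DKO the use of poly(A) sites moved toward the proximal region. The distal region held a median of 60.9% ± 0.480 (SD, n = 4) of the counts of the 2 most used regions in HCT116 and 55.6% ± 0.471 (SD, n = 4) in DKO, a difference of -5.28 percentage points over 6140 loci. With the mean over loci in place of the median the difference was -3.15 points. All 4 DKO libraries, at 55.0% to 56.1%, lay below all 4 HCT116 libraries, at 60.4% to 61.5% (exact permutation test, two-sided, p = 0.0286, the smallest this design allows). With the libraries paired by replicate number the call was lost, with p = 0.125 by exact sign flips, the smallest that 4 pairs allow. The difference was -5.28 points within replicates 1 and 2 and -5.28 points within replicates 3 and 4. The distal share was lower in DKO at 4079 of the loci, or 66.6%.

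Tested locus by locus with edgeR, 1083 loci (17.6%) shifted to the proximal region and 244 (3.97%) to the distal region at an adjusted p under 0.05. Among the proximally shifted loci the median change was -11.0 points. The proximal region rose by a median log2 of 0.71 and the distal region fell by a median of 0.38 on the log2 scale. The loci shifted to the distal region changed by a median of 10.1 points, with a median log2 change of -0.38 at the proximal and 0.79 at the distal region. A change of at least 10 points was found at 585 of the proximal and 123 of the distal shifts. With the replicate number as a block, 1611 loci shifted to the proximal and 406 to the distal region. Within replicates 1 and 2 the numbers were 849 and 204, and within replicates 3 and 4 they were 1225 and 297.

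The 2 regions lay farther apart at the shifted loci. Their median distance was 1437 nt at the proximally shifted loci and 1692 nt at the distally shifted ones, against 723 nt at the 4813 loci without a call. Proximal calls were made at 11.1% of the 605 pairs up to 100 nt apart and at 25.3% of the 1479 pairs between 2000 and 5000 nt apart. Distal calls were made at 0.496% and 6.63% of the same pairs.

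**Figure D2:**
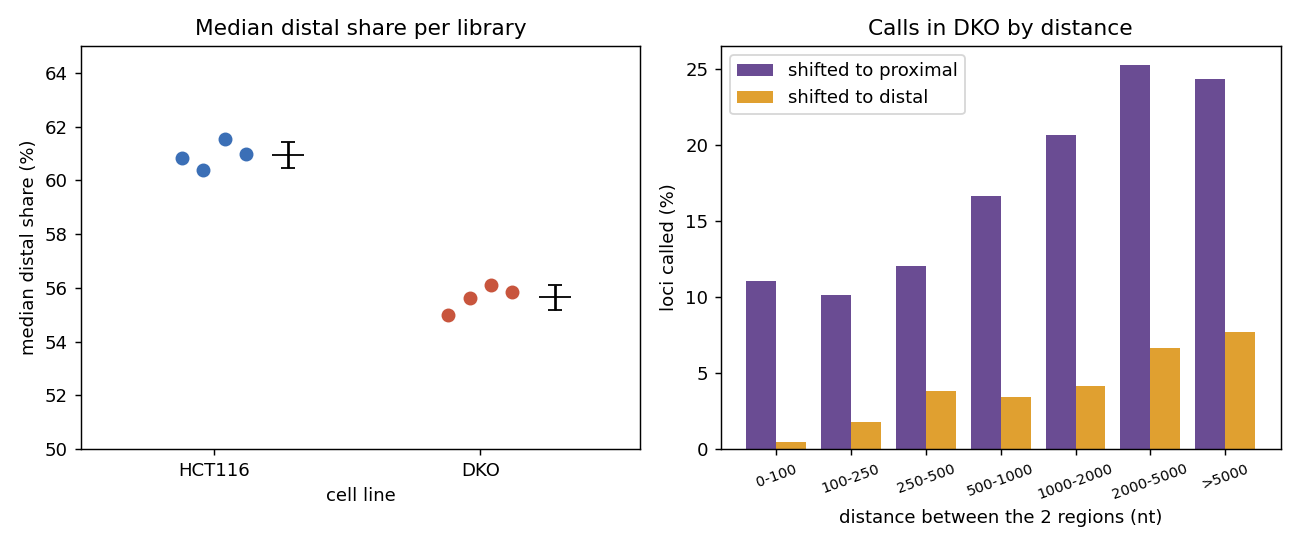
Left, median distal share (percent of the counts of the 2 most used regions) of each library, 1 point per library, with the mean and SD of each line beside them; the vertical axis starts above 0. Right, percent of loci called as shifted to the proximal or the distal region in DKO by the distance between the 2 regions in nt; proximal calls were more frequent than distal calls in every distance bin.

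The test over all regions of a locus called fewer loci, 118 of 6140 at an adjusted p under 0.05 and 534 at an unadjusted p under 0.05 (edgeR, Simes p per locus). The 2 most used regions were tested by an F test per locus, so the tests differ in statistic as well as in regions. Of 18197 regions in the 6140 loci, 115 had a higher and 31 a lower share of their locus in DKO, 146 in all. These counts depended on the split between the replicates. With the replicate number as a block, 1901 loci and 3070 regions changed, and all 118 loci were among them. Within replicates 1 and 2, 728 loci and 1004 regions changed, and within replicates 3 and 4, 1267 loci and 2024 regions. Without DKO replicate 2 the numbers were 66 loci and 80 regions; without HCT116 replicate 3, 75 loci; without DKO replicate 4, 78 loci; and without HCT116 replicate 2, 94 regions. DESeq2 called 1074 loci and 2060 regions, and with locus gaps of 2000 or 10000 nt edgeR called 40 loci and 55 regions or 232 loci and 322 regions.

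Large falls in distal share were measured on chromosomes 16, 4, 19, 1 and 17. On chromosome 16, plus strand, with a proximal region at 56673955-56674013 and a distal region at 56678842-56678856, the distal share was 73.5% ± 18.3 in HCT116 and 2.32% ± 0.369 in DKO (SD, n = 4 here and for each share below). The proximal region there changed by a log2 of 7.22, the distal one by 0.25 and the locus total by 5.16. The distal share fell from 72.2% ± 6.09 to 7.99% ± 3.06 on chromosome 4, minus strand, between regions at 15670029-15670047 and 15669174-15669208. It fell from 92.6% ± 3.35 to 34.0% ± 9.12 on chromosome 19, minus strand, between 54976190-54976225 and 54972905-54972925. On chromosome 1, minus strand, the region at 153516080-153516131 held 98.3% ± 0.279 of the counts in HCT116 and 55.4% ± 3.35 in DKO, against a proximal region at 153519798-153519822. This pair held 2677 counts per library on average, and its locus had an adjusted p of 3.15e-12 (edgeR). On chromosome 19, plus strand, the share of the region at 47113982-47114056 fell from 93.1% ± 1.41 to 58.0% ± 4.02, against a proximal region at 47112528-47112571, with 3472 counts per library and an adjusted p of 2.2e-09 (edgeR).

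Further falls were measured on chromosome 4, minus strand, at the distal region 25749040-25749077 (79.0% ± 2.17 to 42.8% ± 4.45) and on chromosome 17, minus strand, at 76849051-76849086 (75.5% ± 3.25 to 40.4% ± 2.83). The distal region at 180169367-180169443 on the plus strand of chromosome 1 went from 49.4% ± 3.59 to 15.2% ± 2.04. That at 11244472-11244526 on the plus strand of chromosome 19 went from 96.2% ± 0.205 to 64.3% ± 6.52.

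The reverse shift was largest on chromosome 7, minus strand, where the distal region at 100169842-100169861 rose from 25.9% ± 12.03 in HCT116 to 92.7% ± 0.419 in DKO, against a proximal region at 100172274-100172300. Both regions rose there, by a log2 of 1.13 at the proximal and 6.39 at the distal one. The total of that locus rose by 4.05 on the log2 scale. On chromosome 16, minus strand, the share of the region at 67423707-67423726 rose from 10.2% ± 1.09 to 50.8% ± 9.54. Chromosome 17 held 3 of these loci. The distal region at 46685160-46685199, minus strand, went from 4.04% ± 0.611 to 43.8% ± 8.43, while the proximal region at 46689700-46689734 fell by 4.29 on the log2 scale. That distal region changed by a log2 of -0.099 and the locus total by -2.77. The distal region at 61775158-61775188, minus strand, rose from 29.5% ± 4.06 to 68.9% ± 2.77, and that at 7485407-7485437, plus strand, from 3.94% ± 1.84 to 27.2% ± 10.5. At 7485407 the rise followed the split between replicates. Replicates 1 and 2 had 5.31% to 5.73% in HCT116 and 33.2% to 38.8% in DKO. Replicates 3 and 4 had 2.10% to 2.63% in HCT116 and 17.5% to 19.2% in DKO.

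These 14 loci kept an adjusted p under 0.05 without each library in turn (edgeR). The other 3 falls, with changes of -71.4 to -38.4 points, and 7 rises, with changes of 24.6 to 45.0 points, that the rule takes lost it without at least 1 library. Each of the 8 libraries ended at least 2 of these calls, and DKO replicate 2 ended 8. The 2 regions of a locus can belong to neighbouring genes, which the coordinates do not tell. A changed share alone does not show that counts moved from 1 region to the other.

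**Figure D3:**
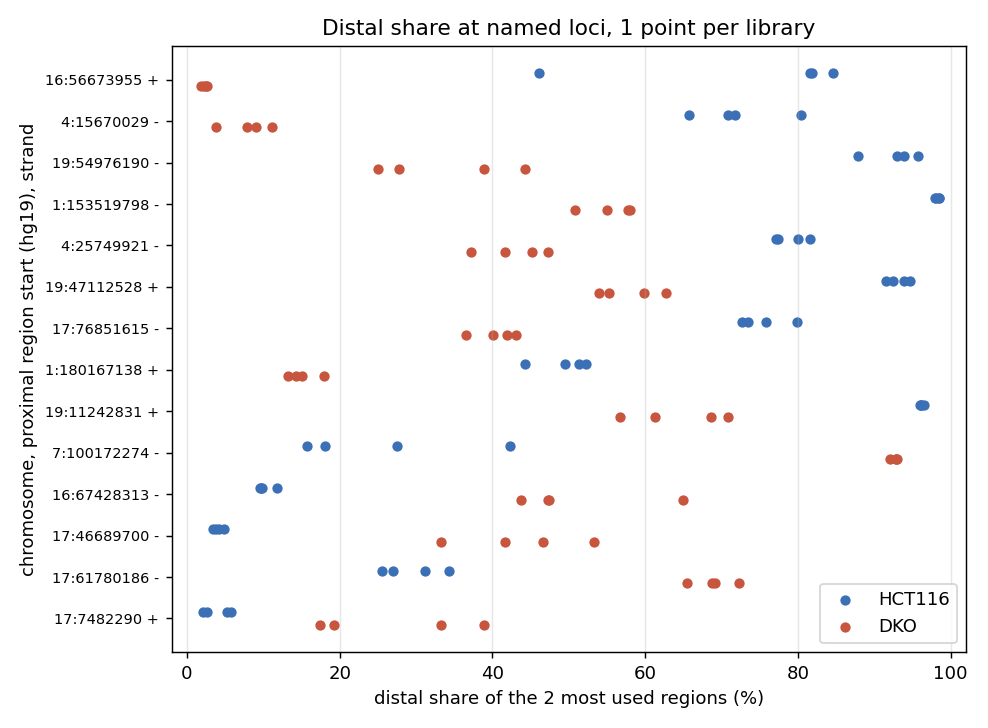
Distal share (percent of the counts of the 2 most used regions) at 14 loci, 1 point per library, HCT116 in blue and DKO in red; each locus is named by chromosome, start of its proximal region on hg19 and strand. The 4 DKO libraries lay apart from the 4 HCT116 libraries at each locus, below them at the 9 upper and above them at the 5 lower loci.

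Locus totals were compared as a measure of transcript abundance in the lines. Totals rose and fell at many loci in DKO, and large rises were more frequent than large falls. Of 17513 loci tested with edgeR, 3838 (21.9%) were higher and 3060 (17.5%) lower in DKO at an adjusted p under 0.05, with median log2 fold changes of 1.37 and -0.89. A fold of at least 2 was reached by 2352 of the higher and 1295 of the lower loci, and a fold of at least 8 by 1191 and 220. The median log2 fold change of all tested loci was -0.03. The 4 DKO libraries lay apart from the 4 HCT116 libraries at 7172 loci, or 41.0%. Free assignment of the 8 libraries to the lines would give 2.86%, a value that leaves out the split between the replicates. With the replicate number as a block, 4975 loci were higher and 5060 lower, so which direction held more loci depended on the block. Within replicates 1 and 2 the numbers were 4861 and 3874, and within replicates 3 and 4 they were 4704 and 4180.

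**Figure D4:**
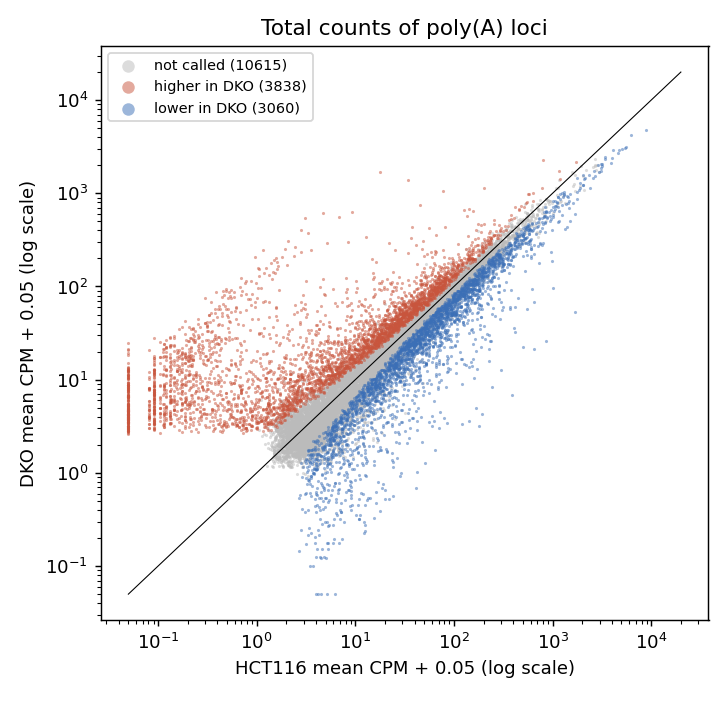
Mean CPM of each tested locus in HCT116 (horizontal) and DKO (vertical), both on log scales after adding 0.05; the line marks equal values and the legend gives the number of loci higher, lower or not called in DKO. Loci at 0 counts in HCT116 form the column at the left, with 189 loci, and those at 0 in DKO the row at the bottom, with 5 loci.

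Loci with few or no counts in 1 of the lines mostly lacked them in HCT116. At 600 of the tested loci the 4 HCT116 libraries together held at most 3 counts, with a median of 88 counts in DKO. At 37 loci the 4 DKO libraries held at most 3 counts, with a median of 99 counts in HCT116. The low-count filter keeps such loci only where all 4 libraries of the other line pass it, so that the lines differ there follows from the filter, and only the 2 numbers are compared. HCT116 had 0 counts at 189 loci and DKO at 5. Of the loci at 0, those in HCT116 were at least 35.4-fold higher in DKO in the median, and those in DKO at least 20.2-fold lower. These 2 bounds cannot be compared in size, since 3 counts stand for a lower level in HCT116, the deeper line. Leaving out DKO replicates 1, 2, 3 or 4 moved the 37 loci to 81, 87, 69 or 68. Without HCT116 replicates 1, 2, 3 or 4 in turn, the 600 loci became 831, 889, 790 or 783. In these fits, and in those within pairs of replicates, the floor of 3 counts was summed over fewer libraries. Within replicates 1 and 2 the numbers for HCT116 and DKO were 864 and 214, and within replicates 3 and 4 they were 973 and 133. They were 809 and 129 without the low-count filter, and 480 and 12 after thinning to equal totals. In all these alternatives only floor loci also called at an adjusted p under 0.05 (edgeR) were counted. The numbers without the filter may therefore leave out floor loci that were not called.

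The 12 loci with the highest fold change all had 0 counts in the 4 HCT116 libraries. The first was a single region on chromosome X at 55250533-55250551, plus strand, with 336 counts and 24.6 CPM ± 10.98 (SD, n = 4) in DKO, at least 178-fold higher. Its DKO level was 13.5 to 17.1 CPM in replicates 1 and 2 and 32.4 to 35.6 CPM in replicates 3 and 4. A locus on chromosome 8 at 144134852-144137994, plus strand, had 304 counts and 21.1 CPM ± 1.10 (SD, n = 4) in DKO, at least 161-fold higher. Loci on chromosome 14 at 106917638-106918015, plus strand, and on chromosome 18 at 25530925-25530952, minus strand, were at least 153-fold and 143-fold higher, with 290 and 271 DKO counts. Those on chromosome 4 at 174432099-174432960, plus strand, and on chromosome 10 at 124909766-124910197, plus strand, were at least 136-fold and 116-fold higher. The other 6 were at least 96.1-fold to 102-fold higher. They lay on chromosome 7 at 134928301-134930536 (minus), chromosome 9 at 38326728-38326750 (plus), chromosome 5 at 2754474-2755513 (plus), chromosome 8 at 96740198-96741619 (minus), chromosome X at 153880245-153880257 (minus) and chromosome 12 at 673459-673469 (minus). Adjusted p-values of these 12 loci ranged from 1.27e-05 to 0.000277 (edgeR).

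Among the loci that fell furthest, a region on chromosome 12 at 51326260-51326301, plus strand, went from 138 counts in HCT116 to 0 in DKO, at least 29.0-fold lower, and a region on chromosome X at 28520036-28520054, minus strand, from 120 to 0, at least 25.2-fold lower. A locus of 5 regions on chromosome 6 at 145249875-145251264, plus strand, was the most abundant, with 384 CPM ± 239 (SD, n = 4) in HCT116 and 6.77 CPM ± 0.847 (SD, n = 4) in DKO, 49.5-fold lower by pooled counts (95% interval 40.5 to 61.2). Its HCT116 level was 171 to 182 CPM in replicates 1 and 2 and 586 to 596 CPM in replicates 3 and 4, and the fold was 29.0 (21.9 to 39.2) in the former and 79.1 (59.2 to 108) in the latter, both outside the pooled interval, which covers counting error only. A locus of 7 regions on chromosome X at 80369383-80370673, minus strand, fell from 40.8 CPM ± 4.81 to 0.645 CPM ± 0.395 (SD, n = 4), 64.9-fold lower (34.1 to 142). Counts fell from 283 to 2 on chromosome 4 at 169108826-169108844, plus strand (89.3-fold, 24.5 to 741), and from 275 to 3 on chromosome 11 at 5341347-5341700, minus strand (57.8-fold, 19.6 to 282). They fell from 320 to 3 on chromosome 11 at 94682353-94682355, plus strand (67.3-fold, 22.8 to 328), and from 108 to 1 on chromosome 10 at 90581097-90582029, minus strand (68.1-fold, 11.97 to 2716). At 94682353 the HCT116 level was 18.8 to 20.2 CPM in replicates 1 and 2 and 4.12 to 6.23 CPM in replicates 3 and 4. With so few DKO counts the fitted log2 fold change moved with single libraries. It went from -6.16 to -8.91 at 169108826 without DKO replicate 4, from -5.74 to -6.50 at 5341347 without DKO replicate 2, from -5.69 to -6.74 at 94682353 without DKO replicate 1 and from -5.69 to -7.57 at 90581097 without DKO replicate 3. Loci on chromosome 12 at 89411219-89411282, plus strand, and on chromosome 10 at 63856683-63856707, plus strand, fell 55.4-fold (21.4 to 204) and 50.5-fold (21.5 to 156). Within the pairs of replicates several of these folds moved by more than 1.5 times, with wide intervals. In replicates 1 and 2 the fold was 32.5 (10.9 to 159) at 5341347, where DKO replicates 3 and 4 had 0 counts. In replicates 3 and 4 it was 39.3 (10.6 to 329) at 169108826 and 35.6 (6.11 to 1436) at 90581097, where DKO replicates 1 and 2 had 0 counts. It was 79.5 (21.8 to 659) in replicates 1 and 2 and 31.3 (5.32 to 1264) in replicates 3 and 4 at 94682353, and 42.8 (14.5 to 209) and 92.4 (16.3 to 3678) at 89411219.

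Shifts in site use and changes in total counts were compared over the 6140 loci with both. Of the 1083 loci shifted to the proximal region, 240 had higher and 329 lower totals in DKO, where independent lists would share 225 and 254 loci. The excess among lower totals had an odds ratio of 1.55 (Fisher's exact test, two-sided, p = 7.3e-09), and for higher totals the odds ratio was 1.11 (p = 0.216). Of the 244 loci shifted to the distal region, 63 had higher and 67 lower totals, against 50.7 and 57.2 for independent lists, with odds ratios of 1.35 (Fisher's exact p = 0.053) and 1.25 (p = 0.143). All 4 odds ratios were above 1. Proximal calls were more frequent at well-counted loci. They were made at 5.71% of pairs at most 1000 nt apart in the lowest of 5 count bins and at 19.1% in the highest. The lists were not matched on counts, so whether the excess reflects the power of the 2 tests was not tested. The same counts enter both calls, loci are not independent replicates, and these 4 p-values are not adjusted.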

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

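Within each line, the 4 libraries were searched for a value far from the other 3 in the loci described singly and in the median distal share. Of 80 sets of 4 values, 6 had such a library. The number computed for chance was about 4, but it does not hold for sets with 0 in 3 libraries. Any count in the remaining library is flagged there, so the 6 cannot be judged against chance.

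On chromosome 16, plus strand, at the pair with a distal region at 56678842-56678856, HCT116 replicate 2 had a distal share of 46.2% (24 of 52 counts, exact 95% binomial interval 32.2% to 60.5%), against 81.6% to 84.6% in the other HCT116 libraries. HCT116 replicate 2 was also flagged on chromosome 16, minus strand, at the distal region 67423707-67423726, with 11.8% (9 of 76 counts, 5.56% to 21.3%). The other libraries had 9.52% to 9.80%, which lie inside that interval. It was flagged again on chromosome 16, plus strand, at the distal region 231165-231185, on a single count. Its share was 2.44% (1 of 41 counts, 0.0617% to 12.9%) where the others had 0%. On chromosome 7, minus strand, at the distal region 100169842-100169861, DKO replicate 4 had 92.1% (1391 of 1511 counts, 90.6% to 93.4%). The other DKO libraries had 92.8% to 92.9%, also inside the interval.

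In the totals, the 2 DKO counts at chromosome 4, 169108826-169108844, were both in replicate 4 (0.757 CPM), and the only DKO count at chromosome 10, 90581097-90582029, was in replicate 3 (0.285 CPM).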

How the results depend on the processing

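The fits within pairs of replicates, the block for these pairs, thinning, other locus gaps, pairs at most 1000 nt apart, limma on log2 ratios and all alternatives for loci at the floor were chosen after the data were examined. No value changed sign, but loci higher in DKO outnumbered lower ones without a block (3838 and 3060) and not with the replicate block (4975 and 5060) or the pairs of replicates as a block (5045 and 5060). Of the summary values under an alternative, 129 stayed within 1.5 times or on their side of the threshold, 41 moved further and 3 lost their call. For loci described singly, 475 values kept their call and 29 lost it, all in usage and all without 1 library. Proximal shifts made up 78.3% to 83.5% of shifts in all settings.

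With the replicate block, 1901 loci and 3070 regions changed usage, 406 loci shifted to the distal region and 5060 were lower in DKO. With the pairs of replicates as a block these were 1843, 2960, 400 and 5060. The block kept 1066 of the 1083 proximal shifts, 237 of the 244 distal shifts, 3835 of the 3838 higher and 3052 of the 3060 lower loci. It kept the calls of all loci described singly and ended that of the median distal share. The difference was -5.28 points with p = 0.125 by exact sign flips of the 4 pairs, and -5.28 points with an exact permutation p = 0.333 within replicates 1 and 2 and within replicates 3 and 4; both are the smallest p these designs allow.

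Within replicates 1 and 2, 728 loci and 1004 regions changed usage, and 214 loci were at the floor in DKO. Within replicates 3 and 4, 1267 loci and 2024 regions changed usage, and 973 loci were at the floor in HCT116 and 133 in DKO; the floor of 3 counts was there summed over fewer libraries. Without each library in turn, changed loci numbered 66 to 93, changed regions 80 to 121, proximal shifts 794 to 1055, distal shifts 168 to 243, higher loci 3519 to 4211, lower loci 2468 to 3032, floor loci 604 to 889 in HCT116 and 35 to 87 in DKO, and the median distal share differed by -5.47 to -5.07 points. It differed by -3.15 points with the mean over loci, -6.20 points with the first and last region and -5.96 points with at least 50 counts in every library.

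DESeq2 called 1074 loci and 2060 regions with changed usage; the cause was not tested. With locus gaps of 2000 nt, 40 loci and 55 regions changed usage and 161 loci shifted to the distal region; with 10000 nt, 232 loci and 322 regions changed usage. A minimum of 10 points left 81 regions, 585 proximal and 123 distal shifts, and a minimum fold of 2 left 2352 higher and 1295 lower loci, by construction. Pairs at most 1000 nt apart, 3271 in number, gave 338 proximal and 73 distal shifts. After thinning to equal totals, 12 loci were at the floor in DKO; the cause was not tested. Without a low-count filter 129 loci were at the floor in DKO and also called lower.

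The shares per region class and the gene list tests (camera, fry) and their alternatives were not run, since regions carried no gene. Depth limits the number of calls: after thinning to the smallest total, 109 loci changed usage, 745 shifted to the proximal and 156 to the distal region, and 3187 were higher and 2519 lower in DKO.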

Other observations

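The tests of the replicate pairs and of near pairs for the proximal shift, and those of chromosome X, of distance against counts and of locus density, were chosen after the result was seen. The other tests, among them thinning and the values within pairs of replicates, were set before their own results were seen but, except for the splits of the 8 libraries, after the data had been examined.

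Loci in crowded parts of the genome tended to be higher in DKO than isolated ones. In 5 bins by the number of tested loci within 500 kb, the median log2 fold change went from -0.19 in the sparsest bin (median of 3 neighbours) to 0.07 in the densest (27 neighbours). The share of loci called higher went from 16.4% to 27.6%, while the share called lower was 17.8% and 17.2%. Among the autosomes and X, the medians were highest on 22 (0.18), 20 (0.11) and 21 (0.09) and lowest on X (-0.18), 13 (-0.17) and 5 (-0.16). The slope of log2 CPM on log2 density was 0.159 higher in DKO, but the slopes of the 8 libraries overlapped between the lines (exact permutation test, two-sided, p = 0.171), which the test as first set, without regard to the split of the replicates, counts against the relation. Within replicates 1 and 2 the difference was 0.170 and within replicates 3 and 4 it was 0.148, with both DKO slopes above both HCT116 slopes each time. Permuting within these pairs gave an exact p = 0.0556, the smallest that the 36 assignments allow, so the relation remains open, and copy number and GC content were not tested.

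The shift of site use toward the proximal region in DKO was weighed first. Greater depth of HCT116 as the whole cause is argued against by the thinned libraries, where the difference in median distal share was -5.65 points against -5.28 unthinned. The split between replicates is argued against by the difference within each pair of replicates (-5.28 points in the pair where it was nearer to 0). Neighbouring genes joined in a locus are argued against only for pairs at most 1000 nt apart, with 4.63 proximal calls per distal call. The near pairs cannot decide this for pairs farther apart, where the explanation stays open. More counts behind distant pairs would not by itself explain the rise of proximal calls with distance, since proximal calls were more frequent beyond 1000 nt in 5 of 5 bins of equal counts. Priming inside transcripts could not be examined without the genome sequence and stays open, as do clonal differences between the lines. That defective DNA methylation may favour proximal sites remains an untested hypothesis.

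The surplus of loci at or under the floor in HCT116 was weighed next. HCT116 was the deeper line, and greater depth lowers the number of loci with few counts. Depth would thus work against this surplus, and thinning could not test it as the cause. The thinned libraries held 480 such loci in HCT116 and 12 in DKO, a ratio of 40. Both lines hold both pairs of replicates, so the split is balanced over them. A surplus confined to 1 pair is argued against by ratios of 4.04 in replicates 1 and 2 and 7.32 in replicates 3 and 4. These 600 loci lay next to each other in 85 cases, against a median of 21 and an upper limit of 31 for the central 95% of 10000 shuffles within 10 bins of mean level (permutation p = 0.0001, the smallest they can give), and 9 of the cases were on opposite strands within 10000 nt, against a median of 1 and a highest value of 7. They were no more frequent on chromosome X, with 18 of 549 loci against 582 of 16953 on the autosomes (odds ratio 0.954, 95% interval 0.557 to 1.54, Fisher's exact test, two-sided, p = 1). Neighbours on one strand can be parts of 1 long gene. Domains that become active together where DNA methylation is defective are a candidate explanation that was not tested, and copy number and clonal differences stay open.

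The split of replicates 1 and 2 from 3 and 4 was the last pattern. Library depth is argued against by the thinned libraries, in which the fewest empty regions in a replicate 3 or 4 were 2.19 times the most in a replicate 1 or 2. The rarer regions by mean share, below the median region, held 1.38 times the share of counts in replicates 1 and 2 of DKO and 1.61 times in those of HCT116, between the bounds of 1.2 and 1.5 set for this test in DKO and above them in HCT116. More reads in rarely used regions could therefore be part of the split but cannot be told apart from other differences between the pairs, for which the labels give no date or batch. No biological explanation was tested, since the split runs across both lines.

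All 35 splits of the 8 libraries into 4 and 4 were fitted. For locus totals only the real split, with 6898 calls, reached that number (1 of 35), the highest of the others being 3028, and for shifts to either region likewise (1 of 35), with 1327 against 739. The share of 1 in 35 treats the libraries as unpaired, so it does not exclude chance for these counts. Only 8 splits part all 4 replicate pairs, too few for a share under 0.05. For changed usage, 2 of 35 splits gave as many calls, so chance cannot be excluded by this count: the real split gave 118 loci and 146 regions, and the highest of the others 492 and 670. In all 4 cases the highest other split was that of replicates 1 and 2 against 3 and 4, which points to a structure of the samples; with the replicate block the real comparison gave 1901 loci and 3070 regions. The other 7 splits that part all 4 replicate pairs mix the lines, and edgeR gave 0 calls in each, with at most 3 loci and 24 regions for usage, 254 shifts and 324 totals at an unadjusted p under 0.05.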
